A study of Rattus norvegicus with 24 samples.

How the data were processed

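Sprague-Dawley rats of both sexes were deafened with kanamycin, an aminoglycoside that kills hair cells, at 400 mg/kg intraperitoneally each day from postnatal day 8 (P8) to P16, and uninjected littermates served as hearing rats, per the labels. Spiral ganglia were taken at P32 or P60, freed of the organ of Corti and divided into an apical and a basal portion, and 4 to 6 ganglia were pooled in a biological replicate. Total RNA was amplified, copied to cDNA, labelled with Cy3 and hybridized to 1-colour NimbleGen arrays. The 24 samples fall into 8 groups of 3 (age, condition and portion). Replicate 1 of every group is on a platform that holds 8 of the samples, and replicates 2 and 3 are on a platform that holds 16.

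The deposited values are intensity values that the authors normalized with RMA, the only tool named in the submitters' processing notes, and its version is not given in the sources used here. Per the labels, the intensity values of technical replicates were averaged into 1 value per biological replicate. The values lie on a linear scale, whereas log2 values had been assumed before the data were examined, so log2 was taken here. The table of the whole series has 14138 transcripts and the tables of the platforms have 26419. All 14138 are in the platform tables, with values that differ by at most 0.002 intensity units. The rule that chose the 14138 is not given in the sources used here. The smallest maximum over samples of a kept transcript was 331.3 and the largest of one left out was 8213, so no single minimum on that maximum separates them. Whether the platforms were normalized together is also not given there. Transcripts were named from a RefSeq table (assembly GRCr8, used for names only). It named 5828 transcripts, 5799 of the 6033 with curated and 29 of the 8105 with predicted accessions, and no gene for the other 8310. The brightest transcript by mean was kept for each of 5750 genes, 61 of which had more than 1.

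The median over transcripts was 1997 to 2263 intensity units per sample, the 75th percentile 5873 to 6363 and the 99th 30090 to 32180. For arrays, the number of arrays limits the precision. The highest correlation between samples was 0.984, for P60 deaf base replicate 1 and P32 deaf base replicate 1. Samples shared at most 1 identical value, so no column of values was a copy of another. This does not test whether the same RNA or array entered more than 1 sample. A main component that held 38.6% of the variance had an r2 of 0.753 with replicate number and 0.342 with platform, and another with 16% had 0.844 with replicate number. Portion had an r2 of 0.471 with the component that held 13.5%.

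Genes were tested with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit, eBayes) on all 24 samples, with 8 group means, platform as an additive term and 15 residual degrees of freedom. Adjusted p is by Benjamini-Hochberg over the 5750 genes, with a threshold of 0.05, and all tests are two-sided. The 12 comparisons were deaf against hearing at P32 and at P60 as the mean of both portions, the same within each portion, base against apex and P60 against P32 within each condition, and the difference of the deafness effect between ages and between portions. An exact test of 3 samples against 3 cannot go below p = 0.1, so no such test was used. A difference is given as log2 ± SE from limma with 3 samples per group, or 6 a side for a mean over 2 groups. Pairs join samples of the same replicate number and otherwise the same labels.

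A total of 33 gene lists was written before the data were examined (neuron, synapse, channel, glia, injury, immune, neighbouring tissue and housekeeping lists, each named with its result). Of their 877 symbols 867 were in the RefSeq table and 493 among the genes tested. The 31 lists with at least 5 tested members were tested with camera of limma at a preset correlation of 0.01, and again with an estimated correlation and with fry. Fry asks whether the genes of a list move on balance in 1 direction and does not compare them with other genes. For every list tested, median, mean and camera direction had the same sign wherever the list passed.

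Genes named in the text follow a rule fixed before the data were examined. For each comparison these are the 6 largest log2 differences in each direction among genes that passed, excluding locus and predicted names. At P32, at P60 and for base against apex in hearing rats, up to 4 members of each list with the smallest p are added. For the differences of the deafness effect they are the 6 genes with the smallest p. For deaf against hearing, Bdnf, Ntf3, Atf3, Gap43, Cd68, Aif1, Cd74, C3, C1qa, Nefh and Syn1 are always included, and 1 more such gene is not reported here. The rule gave 281 genes, of which a part is printed. Any other gene was chosen after its values were seen: Csf1r, C1qb, C1qc, C2, Mag, S100a8, S100a9 and Np4, and the genes named only without P32 hearing apex replicate 1.

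Whether replicate numbers pair the samples was checked as the correlation, over genes, of each sample's deviation from its group. The 63 correlations between samples of the same number outside the P60 deaf apical group were 0.256 to 0.932. Of the 21 with that group, which ran from -0.1 to 0.745, 16 were above 0.1. Averaged by number over the samples of other groups, the correlation was highest for the sample's own number in all 24 samples. Numbers were taken as pairs at P32, in the P60 base and for hearing rats, and the labels do not say what they stand for. Elsewhere (the P60 apex and within deaf rats) pairs of a number only count directions. Portions of the same age, condition and number correlated at 0.596 to 0.932 outside the P60 deaf group, and at 0.688, 0.074 and 0.292 in its numbers 1, 2 and 3. Apical and basal samples of a number are therefore not independent. The fit was tested on simulated data with 200 changed genes: with independent portions it recovered 13.4% of genes changed 1.5-fold, 53.7% of those changed 2-fold and 84.8% of those changed 4-fold, with 2 wrong calls at P60. With correlated portions the shares were 31.3%, 71.6% and 83.3%, with 73 wrong calls at P60 and 5 at P32. Deviations were drawn separately for deaf and hearing samples of a number there, although most of these deviate together in the data.

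The alternatives planned were leaving out the dimmest of 3 equal groups of genes, no platform term, the 16-sample platform alone, the platform tables, another quantile normalization, median centring, sample weights, a trended and robust variance prior, only the groups compared, the mean of a gene's transcripts, every transcript tested, a replicate block, the portions of 1 age, condition and number as a random block, adjusted p under 0.1, at least 1.5-fold, and leaving out each sample. Chosen after seeing the data were a replicate block within each age, that block with the random block, leaving out P32 hearing apex replicate 1 and P60 deaf apex replicate 2 together, the same with the block within age, and every comparison without P32 hearing apex replicate 1. Raw scans were not used here. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.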

Results

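Gene expression was measured with 1-colour arrays in spiral ganglia, which hold the neurons that join the hair cells to the brain. The 24 samples are 3 biological replicates in each of 8 groups: hearing or kanamycin-deafened rats, at P32 or P60, apical or basal portion of the ganglion. The median intensity per sample ran from 1997 to 2263 linear units, and the number of arrays limits the precision. Differences are log2 ratios ± SE for 5750 genes, and P32 hearing apex replicate 1 stands apart in genes typical of deaf and of basal samples. Over all transcripts its mean correlation with its group was 0.847, between replicate 2 (0.825) and replicate 3 (0.87). P32 hearing apex replicate 1 had 9.81 log2 units of Ucn2 against 6.22 and 6.25 in the other P32 hearing apical samples, and 13.40 of Calb1 against 8.20 and 9.62.

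Deaf and hearing ganglia at P60 were compared to ask which genes differ in the ganglion weeks after the hair cells are destroyed. Ucn2, the peptide hormone urocortin 2, was higher in deaf ganglia by 5.11 ± 0.56 log2 units, at 11.60 ± 0.58 (SD, n = 6) against 6.49 ± 0.55, with an adjusted p of 6.99e-05. Gpr83, a G protein-coupled receptor, rose by 4.53 ± 0.43 (adjusted p = 2.49e-05), and Gfra1, the GDNF receptor, by 1.73 ± 0.17 (adjusted p = 3.46e-05). P60 hearing samples were dim for Gpr83 (4.43 to 5.58) and Ucn2 (5.56 to 7.17). Whether such values stand above background was not tested, so the size of both differences is uncertain. Atf3, a transcription factor that injured neurons induce, rose by 3.36 ± 0.50 (adjusted p = 0.00188), from 7.40 ± 0.56 to 10.77 ± 0.58 (SD, n = 6). Hsd17b2, which oxidizes sex steroids, fell by 3.02 ± 0.33 log2 units (adjusted p = 6.99e-05). Its P60 deaf samples were dim too (6.79 to 8.42), so the size of its fall is also uncertain. These 5 genes moved in the stated direction in 6 of 6 pairs of the same number. In the P60 apex and within deaf rats such pairs are no more than a count of directions, since the numbers were not taken to match samples there. The 6 samples of a condition are apical and basal portions of 3 replicates and are not independent. With the portions as a random block, 26 of the 30 named P60 calls ended. These include Atf3 and all immune and injury genes called below except Gfra1.

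**Figure D1:**
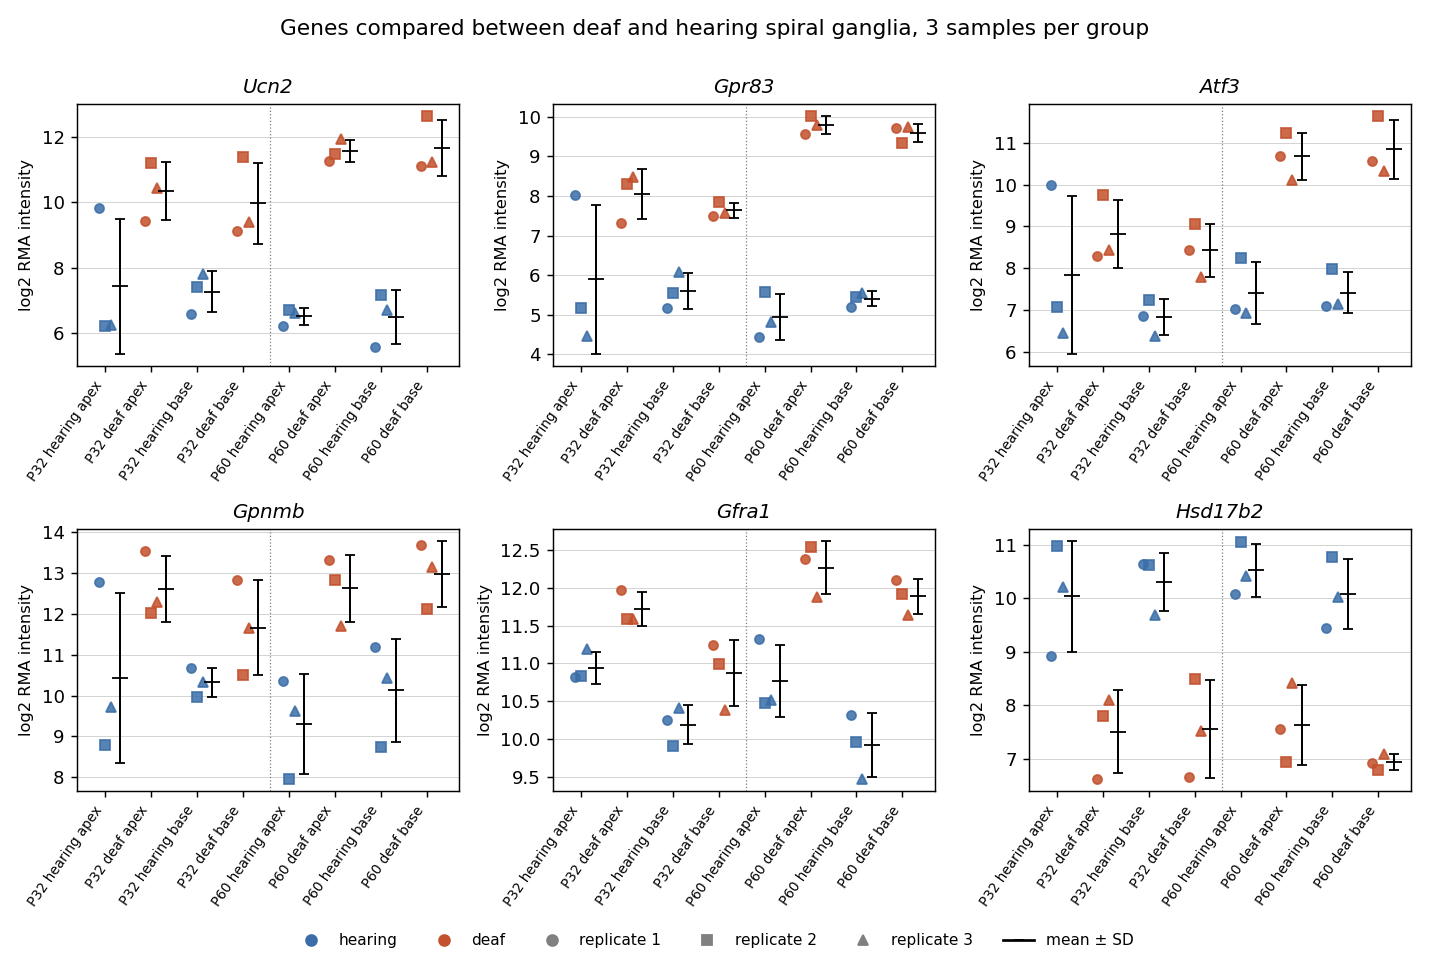
Log2 RMA intensity of Ucn2, Gpr83, Atf3, Gpnmb, Gfra1 and Hsd17b2 in each of the 24 samples, by group, with colour for condition, marker for replicate number, and the mean with its SD over 3 replicates. At P60 the deaf samples lie above the hearing samples for the first 5 genes and below them for Hsd17b2, and P32 hearing apex replicate 1 lies at 9.81 for Ucn2.

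Several immune lists held called genes at P60. Of 18 tested macrophage and microglia genes 5 rose over all genes and 15 adjusted over the list alone, with a list median of 1.16 (adjusted p = 2.16e-16; adjusted p = 0.081 with an estimated correlation), above 0 in 6 of 6 pairs. The 5 were Gpnmb, a glycoprotein of phagocytes (3.08 ± 0.42), Cd68, a lysosomal macrophage marker (1.5 ± 0.22), Laptm5 (1.31 ± 0.30), Adgre1, the F4/80 antigen (1.09 ± 0.25), and Csf1r, the receptor of colony stimulating factor 1 (1.14). Of 23 complement genes 7 rose, and 13 adjusted over the list alone, with a median of 1.0 (adjusted p = 4.02e-12; adjusted p = 0.081 with an estimated correlation). They were C4a (2.09 ± 0.39) and C4b (2.12 ± 0.39), near-identical paralogs that probes can hardly separate, C1s (1.44 ± 0.29), C1qb, C1qc, C2 and Serping1, the C1 inhibitor (0.75 ± 0.16). Of 28 phagocytosis and lysosome genes 4 rose, and 7 adjusted over the list alone, among them Abca1, a cholesterol exporter (1.53 ± 0.26), with a median of 0.42 (adjusted p = 7.45e-11; adjusted p = 0.10 with an estimated correlation). Of 14 MHC class II genes Ifi30 (0.88 ± 0.20) and Ctss (0.71 ± 0.16), which process antigen, rose, and 7 did adjusted over the list alone, with a median of 1.03 (adjusted p = 1.48e-07; adjusted p = 0.15 with an estimated correlation). Of 20 chemokines and cytokines 1 rose, Cxcl14 (2.04 ± 0.41), and 4 adjusted over the list alone, with a median of 0.75 (adjusted p = 1.34e-05; adjusted p = 0.15 with an estimated correlation). Lgals3, the lectin galectin-3 of phagocytes, rose by 2.70 ± 0.40, and Fgg, the fibrinogen gamma chain, by 2.72 ± 0.55. C1qa (1.06, adjusted p = 0.0637), C3 (1.80, adjusted p = 0.0916), Cd74 (1.14, adjusted p = 0.108) and Aif1 (1.27, adjusted p = 0.184) did not pass over all genes.

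Some injury genes rose at P60 as well. Of 13 nerve injury and regeneration genes 3 rose, Atf3, Gadd45a, a growth arrest gene (1.06 ± 0.17), and Hspb1, a small heat shock protein (1.43 ± 0.29), and 8 did adjusted over the list alone. The list median was 0.83 (adjusted p = 2.45e-09), above 0 in 6 of 6 pairs, and this was the only P60 list to pass with an estimated correlation (adjusted p = 0.034). Gap43, a growth cone protein, did not pass over all genes (1.51, adjusted p = 0.0708). Of 13 immediate early genes Fos (1.73 ± 0.26) and Fosl2 (1.32 ± 0.23), which form the AP-1 factor, rose over all genes, and the same number adjusted over the list alone, with a median of 0.72 (adjusted p = 0.000153; adjusted p = 0.095 with an estimated correlation). Of 15 genes of the Schwann cell injury response and satellite glia 1 rose, Btc, an EGF receptor ligand (2.0 ± 0.37), and 7 did adjusted over the list alone, with a median of 0.37 (adjusted p = 0.000274; adjusted p = 0.14 with an estimated correlation). Of 20 neurotrophic factors and receptors Gfra1 alone rose, and the list did not pass (0.18, adjusted p = 0.0872). Bdnf (1.24, adjusted p = 0.285) and Ntf3 (-0.02), the growth factors of these neurons, did not pass. Among 23 apoptosis genes Tnfrsf1a, the TNF receptor 1, rose (0.98 ± 0.22), 2 did adjusted over the list alone, and the median was 0.38 (adjusted p = 0.00136; adjusted p = 0.15 with an estimated correlation).

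Neuronal lists moved down together, without a single member that fell, over all genes or adjusted over the list alone. The median was -0.54 for 21 genes of presynaptic vesicle release (adjusted p = 1.73e-06; adjusted p = 0.15 with an estimated correlation) and below 0 in 5 of 6 pairs. For 25 spiral ganglion neuron identity genes it was -0.36 (adjusted p = 0.000153; adjusted p = 0.15 with an estimated correlation), also below 0 in 5 of 6 pairs. For 18 voltage-gated ion channels of neurons it was -0.53 (adjusted p = 0.000731; adjusted p = 0.15 with an estimated correlation). For 16 glutamate and GABA receptors and postsynaptic density genes it was -0.36 (adjusted p = 0.0222; adjusted p = 0.33 with an estimated correlation). Both were below 0 in 6 of 6 pairs. In the last list Gria1, an AMPA receptor subunit, rose adjusted over the list alone (1.43). Syn2, of synaptic vesicles (-0.79, adjusted p = 0.118), Pclo, of the active zone (-0.98, adjusted p = 0.174), Thy1 (-0.68, adjusted p = 0.185), Syn1 (-0.64) and Nefh, a neurofilament (-0.24), did not pass. Cholesterol synthesis (22 genes) was at -0.35 (adjusted p = 2.14e-05; adjusted p = 0.14 with an estimated correlation) with 0 genes called by limma, and oxidative phosphorylation (20 genes) at -0.14 (adjusted p = 0.00163; adjusted p = 0.27 with an estimated correlation). The 21 Schwann cell and myelin genes had a median of 0.03 (adjusted p = 0.554).

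Other lists at P60 had few or no called genes. Medians were 1.0 for 7 T and NK cell genes (adjusted p = 0.00122; adjusted p = 0.15 with an estimated correlation) and 0.27 for 21 MHC class I genes (adjusted p = 0.00136; adjusted p = 0.21 with an estimated correlation). They were 0.36 for 19 interferon response genes (adjusted p = 0.00267; adjusted p = 0.40 with an estimated correlation) and 0.35 for 11 cell cycle genes (adjusted p = 0.00511; adjusted p = 0.21 with an estimated correlation). Fibroblast and extracellular matrix genes were at 0.39 (adjusted p = 0.00692; adjusted p = 0.15 with an estimated correlation). Cytosolic ribosome genes were at 0.12 (adjusted p = 0.0108; adjusted p = 0.47 with an estimated correlation) and stria and melanocyte genes at 0.56 (adjusted p = 0.0157; adjusted p = 0.25 with an estimated correlation). Not passing were neutrophils and mast cells (0.38, adjusted p = 0.24), cochlear supporting and epithelial cells (0.06, adjusted p = 0.934), and bone and cartilage (0.19, adjusted p = 0.849). Nor did endothelium and pericytes (0.12, adjusted p = 0.411), blood (0.03, adjusted p = 0.793) and heat shock and protein stress (0.05, adjusted p = 0.827) pass. The list for cerebellum and brainstem or skeletal muscle did not pass either (-0.20, adjusted p = 0.113), but its member Myl1, a light chain of fast skeletal muscle myosin, fell by 2.45 ± 0.37 (adjusted p = 0.00188). The interferon median was -0.04 on the 16-sample platform alone, and its call ended without P60 hearing apex replicate 1 (adjusted p = 0.34). The call of the glutamate and GABA list ended without P60 deaf apex replicate 3 (adjusted p = 0.12), and that of the ribosome list without the latter (adjusted p = 0.075) or P60 hearing apex replicate 2 (adjusted p = 0.053). Lists with under 5 tested members were not tested as lists. Of the hair cell list Ocm, a calcium buffer of outer hair cells, was at -3.60 ± 1.0 (adjusted p = 0.0915) and lower in 6 of 6 pairs, while Myo7a (0.74) and Espn (0.19) did not pass. Of 4 B and plasma cell genes Cd37 was at 1.28 (adjusted p = 0.0683).

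The 9 genes lower in deaf ganglia at P60 included Tnmd, a tendon and ligament protein (-3.05 ± 0.52, adjusted p = 0.00562), Cesl1 (-1.29 ± 0.28, adjusted p = 0.0282) and Cntn5, an axonal adhesion protein (-1.15 ± 0.27, adjusted p = 0.037), all lower in 6 of 6 pairs. In total limma called 77 genes, 68 higher and 9 lower, and 708 had an unadjusted p under 0.05. Ucn2, Gpr83, Gfra1, Hsd17b2, Atf3, Gpnmb, Lgals3, Cd68, Fos, Fosl2, Gadd45a, Btc, Abca1, C4a, C4b, Tnmd and Myl1 kept the call whichever of the 12 P60 samples was left out. Fgg lost it without 3 of them (adjusted p up to 0.063), Cxcl14 without 2 (up to 0.065), and Hspb1 and C1s without 5 (up to 0.065). Tnfrsf1a and Cesl1 lost it without 7 (up to 0.10), and Serping1 without 8 (up to 0.085). Laptm5 and Ifi30 lost it without 10 (up to 0.12), and Adgre1, Ctss and Cntn5 without 11 (up to 0.12). The count was 46 without P60 hearing apex replicate 1, 47 without its replicate 3, 29 without hearing base replicate 1 and 42 without its replicate 2. It was 33 without deaf apex replicate 2, 47 without deaf base replicate 1 or 2 and 33 without deaf base replicate 3. It was 171 without P32 hearing apex replicate 1, which enters through the shared spread and the platform term, and these held all 77. Treating the portions of 1 age, condition and number as correlated (0.629) left 4 genes, Ucn2 (adjusted p = 0.048), Gpr83 (0.03), Gfra1 (0.0036) and Hsd17b2 (0.03). With a replicate block within each age added, chosen after the data were seen, that correlation was 0.349 and 46 genes were called. In simulated data with portions correlated at 0.629 the fit made 73 wrong calls. That simulation drew deviations separately for deaf and hearing samples of a number. In the P60 data these deviated together at 0.825 to 0.852 in the base and at -0.011 to 0.511 in the apex. The 73 are therefore not a number of wrong calls to set against the 77. On the 16-sample platform alone 14 genes were called, 12 of them among the 77.

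**Figure D2:**
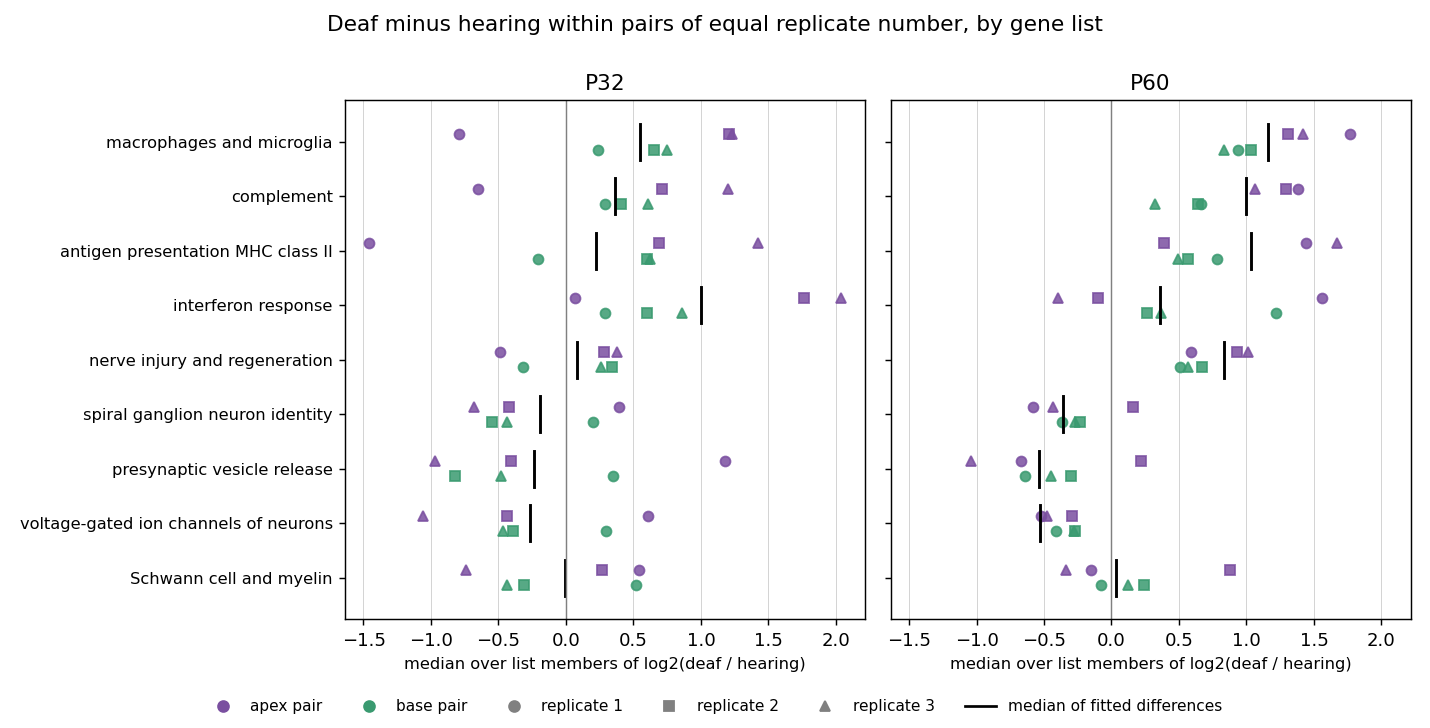
Median over list members of the log2 ratio of deaf to hearing for each pair of samples of the same replicate number (apex and base by colour, number by marker), and the median of the fitted differences as a black line, for 9 gene lists at P32 and P60. Macrophage and complement medians were above 0 in 6 of 6 pairs at P60, and presynaptic medians below 0 in 5 of 6.

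At P32 the same comparison asks for early responses to hair cell loss. A single gene passed: Hsd17b2 was lower in deaf ganglia by -2.65 ± 0.33 log2 units, at 7.53 ± 0.76 (SD, n = 6) against 10.18 ± 0.75, lower in 6 of 6 pairs (adjusted p = 0.00183). Whether its deaf values stand above background was not tested. The interferon response list of 19 antiviral and signalling genes had the largest shift, with a median of 1.0 above 0 in 6 of 6 pairs (adjusted p = 3.84e-20; adjusted p = 0.10 with an estimated correlation). None of its members rose over all genes and 7 did adjusted over the list alone, among them Oasl (2.04 ± 0.62), Oas1b (1.55) and Usp18 (1.58). Macrophage genes had a median of 0.55 (adjusted p = 3.44e-12; adjusted p = 0.11 with an estimated correlation) and complement genes of 0.36 (adjusted p = 2.15e-09; adjusted p = 0.11 with an estimated correlation), each above 0 in 5 of 6 pairs.

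With all samples and no block, no other gene passed at P32. Gpnmb was at 1.76 ± 0.42 (adjusted p = 0.213), Fos at 1.12 ± 0.26 (adjusted p = 0.205) and Cxcl10, an interferon-induced chemokine, at 2.41 ± 0.69 (adjusted p = 0.504), all higher in 6 of 6 pairs. Gfra1 was at 0.72 ± 0.17 (adjusted p = 0.233) and Atf3 at 1.29 ± 0.50 (adjusted p = 1), higher in 5 of 6. Ocm was at -4.69 ± 1.0 (adjusted p = 0.162) and Myl1 at -1.75 ± 0.37 (adjusted p = 0.162). Nefl, a neurofilament, was at -0.52, Bdnf at -0.43 and Nefh at -0.65. Lists that passed with no member called over all genes were T and NK cells (0.67, adjusted p = 3e-05; adjusted p = 0.10 with an estimated correlation), and cell cycle (0.41, adjusted p = 3.66e-05; adjusted p = 0.11 with an estimated correlation). So did MHC class I (0.25, adjusted p = 1.24e-05; adjusted p = 0.15 with an estimated correlation) and chemokines and cytokines (0.21, adjusted p = 2.88e-05; adjusted p = 0.22 with an estimated correlation). Of the last list Ccl7 and Cxcl10 rose adjusted over the list alone. Further lists were phagocytosis and lysosome (0.10, adjusted p = 0.000287; adjusted p = 0.41 with an estimated correlation), of which Gpnmb and Cd68 rose adjusted over the list alone, apoptosis (0.17, adjusted p = 0.00402; adjusted p = 0.26 with an estimated correlation) and MHC class II (0.22, adjusted p = 0.00435; adjusted p = 0.48 with an estimated correlation). Lower were neuron identity (-0.19, adjusted p = 5.06e-05; adjusted p = 0.22 with an estimated correlation) and cerebellum and brainstem or skeletal muscle (-0.41, adjusted p = 0.000287; adjusted p = 0.10 with an estimated correlation). Of the latter Myl1 fell adjusted over the list alone. So were oxidative phosphorylation (-0.11, adjusted p = 0.0115; adjusted p = 0.48 with an estimated correlation), cholesterol synthesis (-0.14, adjusted p = 0.0447; adjusted p = 0.48 with an estimated correlation) and presynaptic release (-0.24, adjusted p = 0.0456; adjusted p = 0.59 with an estimated correlation). Nerve injury (0.08, adjusted p = 0.0838), immediate early genes (0.08, adjusted p = 0.106), ion channels (-0.27, adjusted p = 0.122), glutamate and GABA receptors (-0.13, adjusted p = 0.819) and Schwann cell and myelin (-0.01, adjusted p = 0.587) did not pass. Calls ended without P32 deaf apex replicate 3 for neuron identity (adjusted p = 0.052) and apoptosis (0.075, and 0.055 without P32 deaf base replicate 3). Presynaptic release lost its call without 8 of the 12 P32 samples (adjusted p up to 0.72), cholesterol synthesis without 6 (0.65), and MHC class II (0.54) and oxidative phosphorylation (0.30) without 3.

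The P32 count depended on 1 sample and on how replicate numbers were treated. On the 16-sample platform alone it was 7. A replicate block left it at 1, whereas a block within each age, chosen after the data were seen, gave 12 genes, and 0 with the portions as a random block added. With all samples and no block, 200 genes had an unadjusted p under 0.05 in limma. Without P32 hearing apex replicate 1, left out after its values were seen, 34 genes rose and 4 fell, of which 26 were also called at P60. Ucn2 was then higher by 3.57 ± 0.33 (adjusted p = 1.4e-05; 2.81 and 0.16 with all samples), Gpr83 by 2.71 ± 0.21 (adjusted p = 2.4e-06) and Gpnmb by 2.13 ± 0.38 (adjusted p = 0.018). Atf3 was higher by 1.88 ± 0.36 (adjusted p = 0.026), Fos by 1.40 ± 0.21 (adjusted p = 0.0041), Cd68 by 1.12 ± 0.16 (adjusted p = 0.0041) and Cxcl10 by 3.04 ± 0.63 (adjusted p = 0.033). Ocm was lower (-5.50 ± 0.95, adjusted p = 0.017), as were Hsd17b2 (-2.83 ± 0.35), Myl1 (-2.03 ± 0.36, adjusted p = 0.017) and Kcns3, a potassium channel subunit (-0.79 ± 0.14, adjusted p = 0.021). Ocm stood at 4.33 to 8.16 log2 units in P32 deaf samples. Whether that is above background was not tested, so the size of its fall is uncertain. Gfra1 (0.62, adjusted p = 0.18) and C3 (1.31, adjusted p = 0.31) were not called. Lists then passed with an estimated correlation too: macrophages (0.96, adjusted p = 0.00063), complement (0.63, 0.00094), interferon response (1.34, 0.012) and neuron identity (-0.39, 0.046). So did T and NK cells (0.94, 0.013), MHC class I (0.33, 0.013), chemokines and cytokines (0.49, 0.036) and MHC class II (0.55, 0.046). Nerve injury, which did not pass with all samples, then passed as well (0.19, adjusted p = 0.00095 by camera and 0.013 with an estimated correlation). Leaving out P32 hearing base replicate 3, deaf apex replicate 2 or deaf base replicate 1 gave 2 genes each. The call of Hsd17b2 ended with the portions as a random block, on the 16-sample platform alone and with only the compared groups fitted.

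Within the portions, the deaf against hearing comparison asks where along the cochlea genes respond. In the P60 apex Ucn2 (5.05 ± 0.79, adjusted p = 0.0119), Gpr83 (4.86, adjusted p = 0.00148), Gpnmb (3.31), Atf3 (3.29, adjusted p = 0.0413) and Cd68 (1.79, adjusted p = 0.013) rose. The natural killer cell receptor genes Ly49si1 (3.51) and Ly49i4 (3.46) rose too, all of these in 3 of 3 pairs. Hsd17b2 (-2.89), Myl1 (-2.54) and Adhfe1, a metabolic dehydrogenase (-1.23), were lower. In the P60 base Ucn2 (5.17, adjusted p = 0.00605), Gpr83 (4.19, adjusted p = 0.0055) and Gfra1 (1.97, adjusted p = 0.00169) rose and Hsd17b2 was lower (-3.15, adjusted p = 0.00605), each in 3 of 3 pairs, and all 4 were also called in the apex. Atf3 was at 3.44 ± 0.70 in the base (adjusted p = 0.109) and Cd68 at 1.21 (adjusted p = 0.368), and Bdnf at 2.09 in the apex (adjusted p = 0.244). Apical nerve injury genes had a median of 1.16 (adjusted p = 1.1e-08; adjusted p = 0.046 with an estimated correlation), with 2 risen over all genes and 7 adjusted over the list alone. The basal cholesterol synthesis genes were at -0.38 (adjusted p = 1.25e-09; adjusted p = 0.057 with an estimated correlation).

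The P60 apex had 29 called genes (26 higher, 3 lower; 541 at unadjusted p under 0.05) and the base 4 (3 and 1; 171). The apical count was 2 without hearing apex replicate 1 of P60, 6 without its replicate 2 or 3, and 12, 5 and 13 without deaf apex replicates 1, 2 and 3, and 117 without P32 hearing apex replicate 1. Gpr83 kept its apical call in each of these P60 fits, Ucn2 lost it without hearing apex replicate 1 (adjusted p = 0.062), and Atf3 lost it whichever of the 6 was left out (up to 0.23). Ly49i4 lost it without 2 (up to 0.11), Gpnmb (up to 0.15), Cd68 (up to 0.11) and Hsd17b2 (up to 0.085) without 3, Ly49si1 (up to 0.12) and Adhfe1 (up to 0.085) without 4, and Myl1 without 5 (up to 0.23). The basal count was 2 without deaf base replicate 2, 10 without P32 hearing apex replicate 1, and 7 with a replicate block. Ucn2 (up to 0.089) and Hsd17b2 (up to 0.08) lost the basal call without 2 of the 6 basal samples, and Gpr83 and Gfra1 kept it without each. With the portions as a random block 5 apical genes, Gpr83, Ly49si1, Ly49i4, Cd68 and Gfra1, and 1 basal gene, Gfra1, were called. At P32 limma called 0 genes in the apex (149 at unadjusted p under 0.05, smallest adjusted p 0.239) and 0 in the base (43, smallest adjusted p 0.0975). Without P32 hearing apex replicate 1 there were 11 and 3, among them Ucn2 (4.44 in the apex, 2.71 in the base), Gpr83 (3.37 and 2.04) and Hsd17b2 (-2.90 and -2.76), and without P32 hearing base replicate 3 there was 1 in the base.

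Whether the deafness effect differs between ages or portions was tested directly. By limma 0 genes differed between ages (119 at unadjusted p under 0.05) and 0 between portions (29), with a smallest adjusted p of 1 each. The smallest p for ages belonged to Gfra1 (1.01 ± 0.25 larger at P60), Gpr83 (2.43 ± 0.60), Gadd45a (0.98), Hspb1 (1.6), Plk2, a stress-induced kinase (1.04), and Cxcl14 (1.92), and for portions to Rapgef5 (0.96), Cfap20dc (0.82), Adhfe1 (0.60), Tent5c (0.65), Ccn3 (-0.83) and Igsf1 (1.03). Of the 77 genes called at P60, 76 had the same direction at P32. The nerve injury list rose by 0.98 more at P60 than at P32 (adjusted p = 1.29e-08; adjusted p = 0.036 with an estimated correlation). At P32 that list passed by camera when P32 hearing apex replicate 1 was left out (median 0.19, adjusted p = 0.00095). Without P32 hearing apex replicate 1, 1 gene differed between ages.

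Base and apex of hearing ganglia were compared to ask how expression varies along the cochlea. The base was higher for Bpifa1, a secreted protein of airway and middle ear epithelium (4.91 ± 1.12, adjusted p = 0.0323, 6 of 6 pairs). It was also higher for Calb1, a calcium buffer (2.97 ± 0.56, adjusted p = 0.0114, 5 of 6 pairs), and Rpe65, a retinoid isomerase (2.77 ± 0.46, adjusted p = 0.00666). It was higher for Mog (2.67 ± 0.38, adjusted p = 0.003, 6 of 6 pairs) and Mobp (2.77 ± 0.53, adjusted p = 0.012, 6 of 6 pairs), myelin proteins of oligodendrocytes, and Aqp4, an astrocyte water channel (2.51 ± 0.48, adjusted p = 0.012, 5 of 6 pairs). Mog stood at 13.18 ± 0.39 (SD, n = 6) in the base and 10.51 ± 1.85 in the apex. The largest differences also included Hapln2 (3.15, adjusted p = 0.016), Hoxa2 (3.04, adjusted p = 0.037) and Ermn, an oligodendrocyte protein (2.83, adjusted p = 0.02). Their calls ended without 2, 9 and 5 of the 12 samples. The apex was higher for Fst, the activin antagonist follistatin (-2.26 ± 0.23, adjusted p = 8.11e-05, base lower in 6 of 6 pairs), and Th, of catecholamine synthesis (-1.52 ± 0.36, adjusted p = 0.0419, 5 of 6 pairs). The same was true of Gfra1 (-0.80 ± 0.17, adjusted p = 0.0236) and Dbndd1 (-0.76 ± 0.19, adjusted p = 0.0494).

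**Figure D3:**
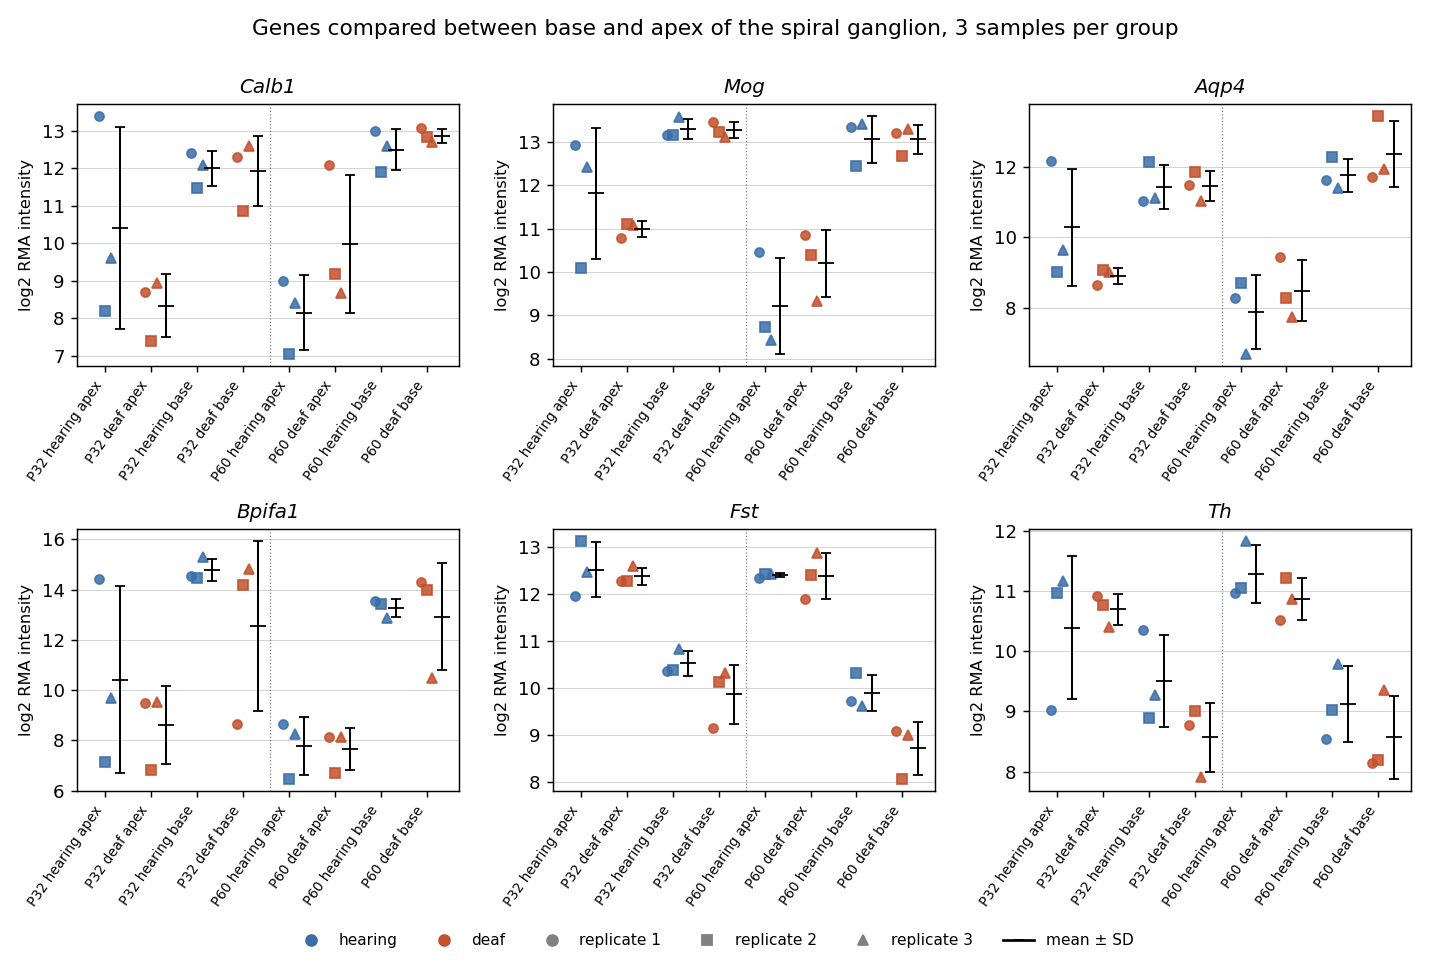
Log2 RMA intensity of Calb1, Mog, Aqp4, Bpifa1, Fst and Th in each of the 24 samples, by group, with colour for condition, marker for replicate number, and the mean with its SD over 3 replicates. P32 hearing apex replicate 1 lies at 13.40 for Calb1, above the basal samples (10.86 to 13.07), at 14.44 for Bpifa1, among them, and at 11.96 for Fst, where the basal samples lie between 8.06 and 10.82.

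In the list for cerebellum and brainstem or skeletal muscle (10 genes, median 0.77, adjusted p = 3.41e-05; adjusted p = 0.041 with an estimated correlation; above 0 in 6 of 6 pairs), Mog, Mobp and Aqp4 rose, over all genes and adjusted over the list alone. These are genes of central glia rather than of muscle. Mog and Mobp also stood in the 21 Schwann cell and myelin genes (median 0.02, adjusted p = 0.0105; adjusted p = 0.42 with an estimated correlation), of which 3 rose, Mog, Mobp and Cldn11, a tight junction protein (1.02 ± 0.23), and 5 adjusted over the list alone, with Mag. The bone and cartilage list (15 genes) shifted up in the base, with a median of 0.21 (adjusted p = 0.000975 by camera, and 0.041 with an estimated correlation). Of its genes 2 were called, Bglap, the bone protein osteocalcin (1.59 ± 0.36), and Alpl, alkaline phosphatase (1.31 ± 0.31), and 4 adjusted over the list alone. Fibroblast and extracellular matrix genes had a median of 0.32 (adjusted p = 5.17e-05; adjusted p = 0.041 with an estimated correlation), with none called over all genes and 2 adjusted over the list alone, among them Col3a1, a fibrillar collagen (0.69). MHC class II genes were at 0.70 (adjusted p = 1.71e-06; adjusted p = 0.23 with an estimated correlation), with Ctss (0.84 ± 0.16) and Cd74, the invariant chain (1.40 ± 0.33), risen and 4 adjusted over the list alone. Macrophages (0.61, adjusted p = 2.74e-06), complement (0.49, adjusted p = 1.4e-05) and neutrophils and mast cells (1.01, adjusted p = 0.00407) each lost the call with an estimated correlation (adjusted p = 0.23). These outcomes depended on P32 hearing apex replicate 1. Without it, macrophages (0.99) and complement (0.87) passed camera with an estimated correlation (adjusted p = 0.017 each). The list with Mog, Mobp and Aqp4 (0.90, adjusted p = 0.065), fibroblast genes (0.41, 0.065) and bone and cartilage (0.11, 0.11) then did not.

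Neuronal lists were lower in the base: presynaptic release (-0.48, adjusted p = 3.41e-05), glutamate and GABA receptors (-0.45, adjusted p = 0.00124) and ion channels (-0.54, adjusted p = 0.00236), below 0 in 5, 6 and 6 of 6 pairs with no gene called. Each had adjusted p = 0.23 with an estimated correlation. Neuron identity genes were at -0.29 (adjusted p = 0.00586; adjusted p = 0.36 with an estimated correlation), although Calb1 rose. Cholesterol synthesis was at 0.22 (adjusted p = 8.51e-05; adjusted p = 0.23 with an estimated correlation), with Tm7sf2 (1.03 ± 0.19) and Sc5d (0.68 ± 0.16), enzymes of that pathway, risen of 22. Cochlear supporting and epithelial cells were at 0.40 (adjusted p = 0.00851; adjusted p = 0.23 with an estimated correlation) with Krt8, an epithelial keratin, risen (1.13 ± 0.27). Phagocytosis (0.19, adjusted p = 0.00124), chemokines (0.45, adjusted p = 0.00242), cell cycle (0.20, adjusted p = 0.032) and nerve injury genes (0.11, adjusted p = 0.0467) had adjusted p = 0.36 with an estimated correlation. In the last list the gene that rose was Gal, the neuropeptide galanin (2.32 ± 0.53), which some neurons also make without injury. Oxidative phosphorylation was at -0.12 (adjusted p = 0.011; adjusted p = 0.42 with an estimated correlation). Fabp7, a fatty acid binding protein of glia, rose (1.59 ± 0.29, adjusted p = 0.0107), and Bdnf (1.80, adjusted p = 0.0845) and Gfap (1.82, adjusted p = 0.0586) did not pass. Without P32 hearing apex replicate 1 the calls of Schwann cell and myelin (adjusted p = 0.33), cholesterol synthesis (0.054) and cell cycle (0.07) ended, and that of Schwann cell and myelin also without P60 hearing apex replicate 2 (0.05). Neuron identity lost its call without P32 hearing apex replicate 2 (0.14), chemokines without its replicate 3 (0.059), oxidative phosphorylation without the latter (0.09) or P60 hearing apex replicate 3 (0.05), and nerve injury (up to 0.36) and cell cycle (up to 0.29) without 6 and 5 of the 12 samples.

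In total 82 genes were higher and 4 lower in the hearing base, and 544 had an unadjusted p under 0.05. Without P32 hearing apex replicate 1 the count was 317, which held all 86, with Calb1 at 3.55 (adjusted p = 0.00024), Bpifa1 at 5.93 (adjusted p = 0.0019) and Th at -1.85. It was 38, 45, 52 and 50 without P32 hearing apex replicate 2 or 3 or base replicate 2 or 3, and 45, 47, 54 and 41 without P60 hearing apex replicate 1 or 3 or base replicate 1 or 3. Fst, Mog, Mobp, Aqp4, Calb1, Rpe65, Fabp7, Ctss and Tm7sf2 kept the call without each of the 12. Bpifa1 lost it without 11 of them (adjusted p up to 0.12), Th (0.15), Gal (0.12), Cd74 (0.15), Cldn11, Krt8, Alpl, Sc5d and Dbndd1 without 10, Bglap without 9 and Gfra1 without 6. A replicate block gave 142 genes. This comparison sets portions of the same age, condition and number against each other, and the main fit ignores their correlation. With the portions as a random block, all 23 named genes kept the call, among them Bpifa1 (adjusted p = 0.0023) and Th (0.0039). Fitting only the compared groups kept 1 of the 23.

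In deaf ganglia the base was higher for Bpifa1 (4.60, adjusted p = 0.0375, 5 of 6 pairs), Fabp4, a fatty acid binding protein (3.69, adjusted p = 0.00174), Tac1, the precursor of substance P (3.56), Ermn, an oligodendrocyte protein (3.37), Calb1 (3.24) and Aqp4 (3.22, adjusted p = 0.00174). The apex was higher for Fst (-3.10 ± 0.23, adjusted p = 5.64e-07, base lower in 6 of 6 pairs), Th (-2.21, adjusted p = 0.00241), Kcnip1, a potassium channel partner (-1.16), Cdh8, a cadherin (-1.14), Smoc1 (-1.03) and Fgf18, a growth factor (-0.94). Of 116 called genes (107 higher, 9 lower; 596 at unadjusted p under 0.05), 60 of the higher and 2 of the lower were called in hearing rats too. Independent calls would give 1.5 and 0.0063, but the comparisons share the estimate of spread per gene and are not independent. Presynaptic release was at -0.54 (adjusted p = 0.000252; adjusted p = 0.47 with an estimated correlation), and the list with Mog, Mobp and Aqp4 at 0.44 (adjusted p = 0.000103; adjusted p = 0.063 with an estimated correlation). The count was 62 without P32 deaf apex replicate 1, 76 without P32 deaf base replicate 3 and 71 without P60 deaf base replicate 2. Kcnip1 lost its call without 11 of the 12 samples, Bpifa1 without 9, and Tac1 and Smoc1 without 8. With the portions as a random block all 12 named genes kept the call, and with only the compared groups fitted 9 did.

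P60 against P32 asks what changes with age. In hearing ganglia Alox15, a lipoxygenase of eosinophils and red cell precursors (-2.64 ± 0.42, adjusted p = 0.0171), Rhd, the Rhesus antigen of red cells (-2.27, adjusted p = 0.0198) and Car3, a carbonic anhydrase (-1.73, adjusted p = 0.0171), were lower at P60. So were Tent5c (-1.01, adjusted p = 0.0171) and Ccn4 (-0.81, adjusted p = 0.0486), all in 6 of 6 pairs. In deaf ganglia Alox15 (-3.32, adjusted p = 0.00185), Rhd (-2.46, adjusted p = 0.00945), Car3 (-1.90, adjusted p = 0.00761), Ccn4 (-0.85, adjusted p = 0.0348), Alas2, of heme synthesis (-1.36, adjusted p = 0.0371), and Slc38a4, an amino acid transporter (-1.27, adjusted p = 0.0482), were lower in 6 of 6 pairs. The conditions shared 4 genes, where independent calls would give 0.0052, although these comparisons are not independent. Blood genes had a median of -0.34 in both, with 1 of 8 fallen in deaf rats over all genes (Alas2) and 3 adjusted over the list alone in each condition (deaf adjusted p = 1.41e-05 and 0.025 with an estimated correlation; hearing 0.00113 and 0.17). Bone and cartilage genes were at -0.27 in deaf (adjusted p = 9.86e-05; adjusted p = 0.021 with an estimated correlation) and -0.32 in hearing rats (adjusted p = 0.00113; adjusted p = 0.073 with an estimated correlation). Neutrophil and mast cell genes were at -1.71 in hearing rats (adjusted p = 0.00113; adjusted p = 0.19 with an estimated correlation), with 4 of 5 fallen adjusted over the list alone, S100a8, S100a9, Lcn2 and Np4.

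Limma called 5 genes with age in hearing (418 at unadjusted p under 0.05) and 6 in deaf ganglia (284). The hearing count was 1 without P32 hearing apex replicate 1, 8 without its replicate 3 and 0 without P32 hearing base replicate 1, P60 hearing apex replicate 3 or P60 hearing base replicate 3. It was 2 without P60 hearing base replicate 1, 1 without its replicate 2 and 9 with a replicate block. The deaf count was 3 without P32 deaf apex replicate 1, 2 or 3, P32 deaf base replicate 2 or 3, or P60 deaf base replicate 1 or 3, 2 without P60 deaf apex replicate 2 and 9 without P32 hearing apex replicate 1. Alox15 and Car3 kept the call in deaf rats without each of the 12 samples. Rhd lost it there without 1 (0.05), Ccn4 without 10 (adjusted p up to 0.15), and Alas2 (up to 0.17) and Slc38a4 (up to 0.2) without 11. In hearing rats Alox15 lost it without 4 samples (up to 0.073), Car3 (up to 0.092) and Tent5c (up to 0.059) without 5, Rhd without 7 (up to 0.092) and Ccn4 without 10 (up to 0.22). With the portions as a random block neither condition had a called gene. A replicate block within each age, chosen after the data were seen, ended all 5 calls in hearing and all 6 in deaf ganglia. That fit compares the ages at their fitted levels for replicate 1, not at group means, so it does not test these calls. The few genes it called were others.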

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

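The tests on P32 hearing apex replicate 1 and on the 9 lower genes and the counts of splits were chosen or run only after the results were seen, and the test of central glia markers was chosen before.

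P32 hearing apex replicate 1 carried transcripts typical of deaf and of basal samples. On the linear scale, from the P60 hearing apical to the P60 deaf basal sample of the same number, its genes higher in deaf rats stood at a median share of 0.82 (0.71 to 0.99), those higher in the base at 1.31 (1.22 to 1.46) and those higher in the apex at 0.73 (0.55 to 0.83). Basal tissue of the same hearing ganglia is argued against, since it would leave the deaf-higher genes at the hearing level, and P32 hearing basal samples stood at 0.18 to 0.36 and the other P32 hearing apical samples at 0.01 to 0.10. The base-higher share lies above the 0.71 to 1.1 of P32 basal samples and the deaf-higher share above the 0.48 to 0.67 of P32 deaf samples. Averaging with 1 of those samples would give like shares no higher than the sample's own, which 1.31 argues against. RNA or an array of some other deaf basal sample averaged into the value (0.82) cannot be told apart from a wrong label for the whole sample (0.73). What keeps this open is that the profile of such a source is not known, and that P32 basal samples themselves stand at 0.71 to 0.91 for the apex-higher genes, although Fst was at 11.96 against 8.06 to 10.82 in basal samples. The design gives no biological explanation for 1 sample of a group, so none was tested.

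Genes of central myelin and astrocytes (Mog, Mobp, Aqp4) were higher in the hearing base, as was Ermn, an oligodendrocyte protein (2.83, adjusted p = 0.02 by limma). A candidate explanation is central glia of the auditory nerve in the basal portion. Of 21 further markers of central glia 9 were tested, none of them in the fixed lists, with a median base-minus-apex difference of 0.38 (0.17 to 1.75) against 0.02 for the Schwann cell and myelin list (permutation p = 0.11, two-sided, 1e+05 permutations over genes). Ptprz1 (1.95), Bcan (1.75) and Gja1 (1.69) led them, limma called 0 of the 9 in hearing rats, and the ganglion's own glia also express several of the 9, so this stays open. A difference along the cochlea within the ganglion is the biological alternative, which was not tested.

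The 9 genes lower in deaf rats at P60, among them Tnmd, Hsd17b2 and Myl1, could have come from organ of Corti tissue left on hearing ganglia. If their whole signal came with outer hair cells, their mean would follow Ocm in hearing samples with a slope near 1. The slope was 0.03 (-0.10 to 0.15) over 12 hearing samples, P32 hearing apex replicate 1 among them, which argues against that. The test does not cover other cells of the organ of Corti or genes that the ganglion also expresses. Loss of other neighbouring tissue, a deafness response and an effect of kanamycin itself stay open and untested.

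Other groupings of the samples were compared with the real one. At P60, 1 of 100 splits, the real one, gave as many genes (77, highest other 1), and for age in deaf rats also 1 of 100 (6 genes, highest other 3). These splits regroup apical and basal samples separately, so chance can be excluded only as far as the portions of a number are independent, which their correlation (0.629) argues against. With both portions of a number regrouped together there are 10 splits, too few for a share under 0.05, with a highest other count of 0 at P60 and 4 for age in deaf rats. For base against apex in deaf rats the real split alone reached its count (1 of 100, 116 genes, highest other 16). The same held among splits that part every pair of a number (1 of 32, the smallest share possible, highest other 0). Both argue against chance, although numbers were not taken to match samples within deaf rats. Base against apex (3 of 100, 86 genes, highest other 287) and age (3 of 100, 5 genes, highest other 805) in hearing rats had a share under 0.05 too. There the numbers pair the samples, and among splits that part every pair, as the real one does, 2 of 32 reached the real count (highest other 197 and 22), so the splits do not exclude chance for either. Of the hearing genes, 60 of the 82 higher in the base were also called in the separate deaf samples (independent calls would give 1.5), and 4 of the 5 for age (0.0052). Both conditions share the estimate of spread per gene, and samples of a number deviate together across conditions, so the overlap is no independent test. Chance is not excluded at P32, where 11 of 100 splits gave as many (1 gene, highest other 2089), and 4 of 32 that part every pair did (highest other 147). For the differences of the deafness effect the real count is 0, which all 100 of 100 splits reach by construction, so they say nothing about chance (highest other 1712 between ages and 986 between portions). Within portions 10 splits are too few for a share under 0.05, with 1 of 10 in the P60 apex (29, highest other 1) and base (4, highest other 0). In the P32 apex (0, highest other 1) and base (0, highest other 0) all 10 reach a count of 0 by construction. The splits with counts several times the real one point to a structure of the samples. At P32 and for age in hearing rats the splits with the highest counts put the samples of replicate 2 together, and for base against apex in hearing rats they exchanged P32 hearing apex replicate 1 with a basal sample. With a replicate block the P32 count was 1, that for base against apex 142 and that for age 9.

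Several lists had a deafness effect that differed between ages by camera. The difference was 0.98 larger at P60 for nerve injury, 0.77 for stria and melanocytes, 0.59 for macrophages, 0.58 for MHC class II and 0.46 for immediate early genes. It was 0.43 for complement, 0.31 for phagocytosis and lysosome, 0.23 for the Schwann cell injury response and satellite glia, 0.18 for the cytosolic ribosome and 0.13 for neurotrophic factors. It was -0.44 for interferon response, -0.33 for presynaptic release, -0.29 for glutamate and GABA receptors, -0.22 for ion channels and -0.20 for cholesterol synthesis. On the 16-sample platform alone the difference was 0.24 for presynaptic release, 0.21 for glutamate and GABA receptors and 0.04 for MHC class II. Those 3 of the 15 calls reversed there and 5 others ended. A replicate block ended 3 of the 15 calls, and a block within each age also 3. With an estimated correlation nerve injury had an adjusted p of 0.036 and the others of 0.35 to 0.38. Without P32 hearing apex replicate 1 the calls of presynaptic release (-0.07, adjusted p = 0.061), glutamate and GABA receptors (-0.11, adjusted p = 0.22) and ion channels (-0.13, adjusted p = 0.23) ended. Stria and melanocytes lost the call without 13 of the 24 samples (adjusted p up to 0.26), neurotrophic factors (up to 0.44) and glutamate and GABA receptors (up to 0.29) without 8, ion channels without 7 and interferon response without P32 hearing apex replicate 3 (0.051).

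Between portions several lists differed too. The deafness effect in the base minus that in the apex was negative for immediate early genes (-0.51), complement (-0.35), fibroblast and extracellular matrix (-0.35), macrophages (-0.24), cholesterol synthesis (-0.23), cell cycle (-0.20), chemokines and cytokines (-0.18), bone and cartilage (-0.17) and phagocytosis (-0.09). With an estimated correlation the fibroblast list had an adjusted p of 0.027, bone and cartilage of 0.05 and the rest of 0.13 to 0.84. A replicate block ended 2 of the 9 calls, a block within each age 3, and the 16-sample platform alone 2. Macrophages (adjusted p up to 0.85) and phagocytosis (up to 0.62) lost the call without 17 of the 24 samples, chemokines without 13 (up to 0.61), cell cycle without 11 (up to 0.38) and bone and cartilage without P60 hearing apex replicate 3 (0.099), hearing base replicate 2 (0.074) or deaf base replicate 3 (0.078). Immediate early genes lost it without P60 deaf apex replicate 2 (-0.34, adjusted p = 0.15) and cholesterol synthesis without P32 hearing apex replicate 1 (-0.14, adjusted p = 0.13).

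Data outside the tested genes held called differences too. Of 8310 transcripts that name no gene, limma called 35 for deaf against hearing at P60 (30 higher, 5 lower) and 26 for base against apex in hearing rats (all higher). Of 3877 genes found only in the platform tables, 13 were called at P60 and 23 for base against apex in hearing rats. These genes are not in the table of the whole series, and whether they stand above background was not tested, so no fold is given for them.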

How the results depend on the processing

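Alternatives with a replicate block within each age, or with P32 hearing apex replicate 1 and P60 deaf apex replicate 2 left out, were chosen only after the results were seen. The median of all genes moved by at most 0.092 log2 units under another scaling. Of 1728 values of 80 called list results 1402 kept direction and call, 322 lost the call and 4 reversed, and of 2530 values of 92 called results of named genes 1858 kept both, 672 lost the call and 0 reversed. The reversals were on the 16-sample platform alone: interferon response at P60 (-0.04) and, for the difference between ages, presynaptic vesicle release (0.24), glutamate and GABA receptors (0.21) and MHC class II, which reversed only against the other genes, since its median stayed above 0 (0.04). Arrays limit these results by the number of samples and by signal over background for dim genes.

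The counts with all samples are 1 at P32 and 77 at P60, 0 and 0 in the P32 apex and base, 29 and 4 in the P60 apex and base. They are 86 and 116 for base against apex in hearing and deaf rats, 5 and 6 for age in hearing and deaf rats, and 0 for both differences of the deafness effect. Counts that moved by over 1.5 times follow, and for these the cause was not tested, except that fewer genes, fewer samples or a looser threshold change a count by construction. Without the dimmest genes the count was 0 at P32, 1 in the P60 base, 51 and 64 for base against apex in hearing and deaf rats, and 0 and 2 for age. With no platform term it was 36 at P60, 14 in its apex, 56 and 70 for portion, and 0 and 1 for age. On the 16-sample platform alone it was 7 at P32, 14 at P60, 6 in the P32 apex, 3 and 2 in the P60 apex and base, 54 and 29 for portion, and 2 and 2 for age. The platform tables gave 176 for portion in deaf rats, 10 for age in deaf rats and 1 for the difference between ages. Another quantile normalization gave 7 in the P60 base and 2 for age in hearing rats, a trended and robust prior 47 in the P60 apex and 3 for age in hearing rats, and every transcript tested 3 for age in deaf rats. Sample weights gave 1438 at P60, 1 and 1 in the P32 apex and base, 818 and 645 in the P60 apex and base. They gave 191 and 491 for portion, 76 for age in deaf rats and 1 for the difference between ages, with a weight of 24.5 for P60 hearing base replicate 1 and 13 for P60 deaf apex replicate 1. Fitting only the compared groups gave 0 at P32, 239 at P60, 3 and 1 in its apex and base, 1 for portion and 0 for age in hearing rats. An adjusted p under 0.1 gave 146 at P60, 1 in the P32 base, 65 in the P60 apex and 141 for portion in hearing rats.

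A replicate block gave 178 at P60, 83 and 7 in its apex and base, 142 for portion in hearing rats, and 9 and 14 for age. The portions as a random block gave 0 at P32, 4 at P60, 5 and 1 in its apex and base, 540 and 590 for portion, and 0 and 0 for age. A replicate block within each age gave 12 at P32, 271 at P60, 1 in the P32 apex, 124 and 8 in the P60 apex and base, 205 and 267 for portion, and 1 and 2 for age. That block with the random block gave 0 at P32, 46 at P60, 70 in its apex, 475 and 506 for portion, and 1 and 1 for age. Leaving out P32 hearing apex replicate 1 and P60 deaf apex replicate 2 gave 38 at P32, 145 at P60, 17 and 3 in the P32 apex and base, 79 and 14 in the P60 apex and base, 339 for portion and 1 for age in hearing rats, and 16 lists for the difference between portions. The same with the block within each age gave 288 at P32, 727 at P60, 139 and 5 in the P32 apex and base, 368 and 92 in the P60 apex and base, 1089 and 443 for portion, 3 for age in hearing rats and 1 for the difference between portions. Where a block within each age was fitted, the counts for age compare fitted levels of replicate 1, not group means. They therefore do not test the age calls.

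Leaving out each sample of the groups compared gave 1 to 38 genes at P32, 29 to 72 at P60, 0 to 11 and 0 to 1 in the P32 apex and base, 2 to 13 and 2 to 4 in the P60 apex and base. It gave 38 to 317 and 62 to 103 for portion in hearing and deaf rats, 0 to 8 and 2 to 5 for age, and 0 to 1 and 0 to 0 for the differences between ages and portions. Leaving out P32 hearing apex replicate 1 where it was outside those groups gave 171 at P60, 3 in the P32 base, 117 and 10 in the P60 apex and base, and 159 for portion and 9 for age in deaf rats. Lists called were 15 at P32 (11 to 17), 22 at P60 (21 to 23), 19 for portion in hearing rats (16 to 20), 15 for the difference between ages (13 to 19) and 9 for that between portions (4 to 16). With all samples and an estimated correlation they were 0, 1, 3, 1 and 1, and with fry 0, 11, 3, 0 and 0.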

Other observations

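Of the hair cell list 12 genes had values in the tables of the platforms. Ocm had a mean of 10.09 log2 units in hearing samples against 5.94 in deaf ones. Limma called it at neither age with all samples, and whether its deaf values stand above background was not tested. Myo7a (8.15 against 8.57) and Espn (9.16 against 9.29), also among the genes tested, were not lower in deaf samples. The rest were not among the genes tested, and limma on the platform tables called none of them. Most had lower means in deaf samples, such as Cdh23 (7.12 in hearing against 6.16 in deaf samples), Ptprq (5.82 against 4.62) and Slc26a5 (5.57 against 4.59). Gfi1 (6.94 against 7.06) and Xirp2 (4.11 against 4.26) did not. These genes were dim, and whether they stand above background was not tested.

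In P60 deaf rats the apical and basal samples of replicate 2 deviated from their groups with a correlation of 0.074, and those of replicates 1 and 3 with 0.688 and 0.292, against 0.596 to 0.932 in the other groups.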
